A study of Oryza sativa with 8 samples.

How the data were processed

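RNA of whole rice seedlings was extracted with a plant RNA kit, labelled with 1 dye (Cy3) and hybridised to a custom expression array, per the labels. The deposited scanner tables were made by the authors with Feature Extraction 10.7.1.1, and per the file headers the values used here are processed signal intensity: background-subtracted and detrended within each array, not logged and not scaled between arrays. The deposited table of series values held the same intensity on all 8 arrays (100% of values equal). The deposited flag columns (well above background, outlier, saturated, control) are of the kind other than a measurement, 0 or 1 for each spot. The design was built on the IRGSP5 genome, per the file headers. All 8 arrays lay on 1 slide read in 1 scan, with Nipponbare in slide row 1 and Pokkali in row 2, the 0 h arrays in columns 1 and 2 and the 8 h arrays in columns 3 and 4. Array position and group therefore cannot be told apart, and a slide or scan block could not be fitted. One 8 h Nipponbare sample is called replicate 2 by its title and source and replicate 1 by its description; the title was used.

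Control spots (1319 per array) and spots with an outlier flag were left out. The log2 intensity of the 61657 non-control spots was shifted so that the 75th percentile of each array was 0, and spots of the same probe were averaged, including 459 probes printed 15 or 16 times, whose spots had a median SD of 0.0714 to 0.0814 log2 units within an array. Of 55078 probes, 47559 were well above background on both arrays of at least 1 group and were kept; 7519 were left out. For a repeated probe, a share of spots above 0.5 had to be well above background, a rule chosen after the data were seen. Probes of the same locus were averaged (2147 loci had 2 or more kept probes), which gave 45411 loci of the 52795 on the array. The number of arrays limits the precision: groups of 2 allow no smaller two-sided exact permutation p than 0.333, so no test on single genes was made outside limma.

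A model with the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes; 4 residual degrees of freedom, 2.36 prior degrees of freedom, prior SD 0.212 log2 units). The contrasts were 8 h against 0 h in each line, their difference (Pokkali change less Nipponbare change), and Pokkali against Nipponbare at each time. A locus passed at a Benjamini-Hochberg adjusted p under 0.05 over all loci of a contrast, and all tests were two-sided. Where a locus was not well above background on any array of 1 of the groups compared, a bound is given: the values of that group were raised to the lowest value that any probe well above background had on the same array, and the difference from the other group was taken from there. Such a locus is called at least N-fold higher or lower, with the adjusted p of the fit, and no fold is given where both groups were dark. Tested on simulated data with 2 arrays per group, the fit recovered 2.99% of 2-fold, 59.7% of 4-fold and 84.8% of 16-fold salt changes. It recovered 0%, 34.3% and 81.8% of such interactions, and called 0.00886% and 0.0133% of unchanged genes. In each simulation only 67, 67 and 66 of 45335 genes were changed by these folds, whereas 26.3% of loci passed for salt in Nipponbare. With more changed genes the adjusted threshold is less strict, so the salt shares give neither the recovery nor the share of unchanged genes called in these data. The simulated noise was also independent between arrays, with the same SD of a gene in all groups, unlike the 0 h replicates here.

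Before the data were examined, 35 gene lists, the contrasts, the alternatives and the rule for named genes were fixed. The arrays name probes only by transcript model, and the reference gene table matched 0 of these identifiers. Gene names therefore rest on locus identifiers fixed beforehand from general knowledge, not on an annotation: 14 lists had such identifiers (68 loci, 65 of them measured) and 21 had none and were not analysed here. The 14 are LEA and dehydrin, abscisic acid, proline and trehalose, sodium and potassium transport, DREB (AP2/ERF), NAC, WRKY, bZIP, TIFY, light harvesting and photosystem, Rubisco small subunit (Calvin cycle), nitrate, root-enriched and known salt genes. A list of 9 clock loci was added after the data were seen, before its own values were computed. Adjusted over the list alone means Benjamini-Hochberg adjustment within the list. The 6 lists with at least 5 measured loci were tested as sets with camera (preset correlation 0.01), with an estimated correlation, and with fry, adjusted over the 6. The rule took, per contrast, the loci with the largest rise and fall among those that passed, lay apart in all replicates and were above background in both groups (2 per direction, since they have no names), the 2 members of each list with the smallest p, and all known salt genes. The condition on background asked for at least 1 array of each group and was not in the rule as fixed. It cut the eligible interaction calls from 157 to 78 and the line calls at 0 h from 7628 to 6083.

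The alternatives were quantile normalisation, median scaling, no scaling, no filter on dim probes, probes bright on all 8 arrays, only the arrays of the groups compared, replicate number as a block, a variance trend with robust estimation, single probes, the brightest probe of a locus, a 2-fold minimum, outlier spots kept, and leaving out each array in turn. A planned background correction (normexp) on mean signals could not be run on the columns held; normexp with an offset of 50 on the deposited median foreground and background intensity took its place after the data were seen. Leaving out replicate 2, or replicate 1, of both lines at 0 h, and a replicate block within each time, were also added then. The block within each time was first coded with replicate 1 as the baseline, which took its salt changes from replicate 1 alone; it was recoded around the group means after those values had been seen. Leaving out 1 array leaves a group with a single array, whose spread is taken to be that of the other groups. Leaving out the same replicate of both lines at 0 h leaves the 8 h pairs alone to give the spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. How the plants of replicates 1 and 2 were grown and sampled is not given in the sources used here.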

Results

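Transcript levels were measured in whole seedlings of 2 rice lines, the japonica line Nipponbare and the indica line Pokkali, at 0 h and after 8 h in 250 mM NaCl. Each of the 4 groups held 2 biological replicates of 14-day-old plants, and each replicate was hybridised to its own one-colour array, giving 8 arrays. Between 81.0% and 85.5% of the 61657 non-control spots of an array were well above background, and the 75th percentile of the signal lay between 674 and 950 intensity units. The tests covered 45411 loci. Replicates differed by an SD over loci of 0.62 log2 units in Nipponbare at 0 h and 0.63 in Pokkali at 0 h, against 0.44 and 0.45 at 8 h. Fits without the same replicate of both lines at 0 h take their spread from the narrower 8 h pairs alone. Their p-values for comparisons that involve 0 h therefore tend to be too small, and calls gained there are no evidence of more changes. Seedlings kept for 8 h without salt were not among the groups, so each change from 0 h to 8 h holds both the salt and the time of day.

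The first comparison asked which transcripts differed in Nipponbare between 0 h and 8 h of salt. Transcripts of proteins that protect cells during drying rose steeply. RAB16C (LOC_Os11g26760), a dehydrin, rose 53.0-fold (log2 5.73, SE 0.35, n = 2 arrays per group, adjusted p = 0.00103 by limma), and LEA3 (LOC_Os05g46480), a late embryogenesis abundant protein, rose 34.0-fold (SE 0.73 log2 units, adjusted p = 0.00543). SALT (LOC_Os01g24710), a mannose-binding lectin, rose 22.5-fold (adjusted p = 0.00161). RAB16A (LOC_Os11g26790) was not above background on either 0 h array and rose at least 11.2-fold (adjusted p = 0.00155). Of the 6 LEA and dehydrin loci 4 rose, 5 adjusted over the list alone. The remaining members were DHN1 (LOC_Os02g44870) at a log2 change of 0.69 (adjusted p = 0.0856) and RAB16D (LOC_Os11g26750), which was above background on only 1 of the 4 Nipponbare arrays. The list shifted upwards as a set (camera adjusted p = 0.00161; adjusted p = 0.0668 with an estimated correlation). Of 16 measured genes with a known part in salt responses, all but 2 of them members of other lists, 9 rose and 10 rose adjusted over the list alone (camera adjusted p = 9.35e-05; adjusted p = 0.0668 with an estimated correlation). Without Nipponbare 8 h replicate 2 the count of risen genes was 5, and without Nipponbare 0 h replicate 1 TPP1 (LOC_Os02g44230) passed as lower (adjusted p = 0.0459; 0.00432 to 0.671 over all alternatives).

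Enzymes of abscisic acid synthesis also rose in Nipponbare. NCED5 (LOC_Os12g42280), a 9-cis-epoxycarotenoid dioxygenase that makes the precursor of the hormone, rose 5.15-fold (log2 2.36, SE 0.18, adjusted p = 0.0013). NCED3 (LOC_Os03g44380) rose 5.93-fold (adjusted p = 0.0233) and NCED4 (LOC_Os07g05940) 22.8-fold (adjusted p = 0.0338). The 3 abscisic acid 8'-hydroxylases, which break the hormone down, did not pass: ABA8OX1 (LOC_Os02g47470) was at a log2 change of -1.28, ABA8OX2 (LOC_Os08g36860) at -0.10 and ABA8OX3 (LOC_Os09g28390) at -2.01. The 0 h replicates lay apart for this list too: its mean was -0.89 on Nipponbare 0 h replicate 1 and 0.98 on replicate 2, against 0.94 and 1.17 at 8 h. Thus 3 of 6 loci rose, and 3 adjusted over the list alone; the list did not pass as a set (camera adjusted p = 0.284; adjusted p = 0.643 with an estimated correlation). It passed without Nipponbare 0 h replicate 2 (0.0237; adjusted p = 0.288 with an estimated correlation) and without replicate 2 of both lines at 0 h (0.0284; adjusted p = 0.233 with an estimated correlation), in a range of 0.0237 to 0.985. The count of risen loci was 1 without Nipponbare 0 h replicate 1 (NCED3 adjusted p = 0.0595, NCED4 0.0936), without Nipponbare 8 h replicate 1 (0.0836 and 0.0936) and without Nipponbare 8 h replicate 2 (0.113 and 0.157). The NCED4 call also ended without either Pokkali 8 h replicate (adjusted p = 0.0614 each) and with the 4 Nipponbare arrays alone (0.0545). Without Nipponbare 0 h replicate 1, ABA8OX3 passed as lower (adjusted p = 0.0381), and without replicate 1 of both lines at 0 h ABA8OX3 (0.00464) and ABA8OX1 (0.00528) did. Over all alternatives the adjusted p ran from 0.00275 to 0.113 for NCED3, from 0.00205 to 0.157 for NCED4, from 0.00528 to 0.915 for ABA8OX1 and from 0.00464 to 0.686 for ABA8OX3.

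Sodium export and sequestration genes and NAC transcription factors rose in Nipponbare as well. NHX1 (LOC_Os07g47100), the vacuolar sodium/proton antiporter, rose 2.91-fold (SE 0.26 log2 units, adjusted p = 0.00868), and SOS1 (LOC_Os12g44360), the plasma membrane antiporter, rose 2.08-fold (adjusted p = 0.00703). HKT2;1 (LOC_Os06g48810) and HKT1;1 (LOC_Os04g51820) did not pass, so 2 of the 4 measured transport loci rose, and 2 adjusted over the list alone. Without replicate 1 of both lines at 0 h HKT2;1 passed as higher (adjusted p = 0.00713; 0.00713 to 0.752 over all alternatives) and HKT1;1 as lower (0.0142; 0.0142 to 0.892). The SOS1 call ended without Nipponbare 8 h replicate 2 (adjusted p = 0.0534; 0.0047 to 0.0534 over all alternatives), which left 1. NAC10 (LOC_Os11g03300) rose 11.7-fold (SE 0.26 log2 units, adjusted p = 0.00125), NAC5 (LOC_Os11g08210) 4.09-fold (adjusted p = 0.00216) and NAC6 (LOC_Os01g66120) 2.94-fold (adjusted p = 0.0288), so 3 of 4 NAC loci rose, and 4 adjusted over the list alone. SNAC1 (LOC_Os03g60080) was at a log2 change of 1.63 (adjusted p = 0.121) and passed without replicate 2 of both lines at 0 h (0.0155; 0.00605 to 0.4 over all alternatives). The NAC6 call ended without Nipponbare 0 h replicate 1 (adjusted p = 0.0986), without Nipponbare 8 h replicate 2 (0.152), without either Pokkali 8 h replicate (0.0516 each) and with the Nipponbare arrays alone (0.0596), and ran from 0.00437 to 0.152 over all alternatives. Of 3 bZIP loci, BZIP46 (LOC_Os06g10880) rose 2.01-fold (adjusted p = 0.0141), 1 adjusted over the list alone. That call ended without Nipponbare 0 h replicate 2 (0.0638), 8 h replicate 1 (0.0713) or 8 h replicate 2 (0.0737), and ran from 0.00692 to 0.0737 over all alternatives. Without either Pokkali 0 h replicate BZIP72 (LOC_Os09g28310) passed too, which made 2 (adjusted p = 0.0423 each; 0.0208 to 0.404 over all alternatives).

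Photosynthesis and root transcripts fell in Nipponbare. Of 14 light harvesting and photosystem loci 13 fell, and 13 adjusted over the list alone, with a median log2 change of -2.44 over the 14 (camera adjusted p = 9.77e-10; adjusted p = 0.0668 with an estimated correlation). LOC_Os07g37550, a chlorophyll a/b binding protein, was at -2.80 (SE 0.17, adjusted p = 0.00103), and PSBO (LOC_Os01g31690), of the oxygen-evolving complex, at -1.86 (SE 0.24, adjusted p = 0.00422). PSBS (LOC_Os01g64960), needed for the dissipation of excess light, was at -4.11 (SE 0.69, adjusted p = 0.00877), a call that ended without Nipponbare 8 h replicate 2 (0.0564; 0.00341 to 0.0564 over all alternatives). All 3 measured loci of the 4 Rubisco small subunits fell, and 3 adjusted over the list alone: LOC_Os12g19470 was at -3.97 (SE 0.60), LOC_Os12g17600 at -3.15 (SE 0.32) and LOC_Os12g19381 at -2.55 (SE 0.19). Of 7 root-enriched loci 4 fell, and 4 adjusted over the list alone (camera adjusted p = 0.00748; adjusted p = 0.0668 with an estimated correlation). These were RCC3 (LOC_Os02g44310) at -4.68 (SE 0.44, adjusted p = 0.00186), the silicon channel LSI1 (LOC_Os02g51110) at -1.32 (SE 0.17), the nitrate transporter NRT2.2 (LOC_Os02g02190) at -3.10 (SE 0.31) and the iron transporter IRT1 (LOC_Os03g46470), at least 1.24-fold lower (adjusted p = 0.0107). The IRT1 call ended with another background correction (0.262), without Nipponbare 0 h replicate 2 (0.0516) and without Nipponbare 8 h replicate 1 (0.0586), and ran from 0.00738 to 0.262 over all alternatives. NRT2.2 was also the 1 of 2 nitrate loci that fell, and the 1 adjusted over the list alone; NRT2.1 (LOC_Os02g02170) was not above background on any Nipponbare array.

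Several stress lists held few or no calls in Nipponbare. None of the 4 DREB loci, 3 WRKY loci or 4 TIFY jasmonate repressors passed, and 0 of each passed adjusted over the list alone. The 0 h replicates lay far apart for these genes: the TIFY mean was -1.64 on Nipponbare 0 h replicate 1 and 1.33 on replicate 2, against -0.64 and -0.16 at 8 h, and the WRKY mean was -0.85 and 1.23. Leaving out replicate 2 of both lines at 0 h gave 2 risen TIFY, 2 risen WRKY and 1 risen DREB loci. Leaving out replicate 1 of both gave 2 fallen TIFY, 2 fallen WRKY and 2 fallen DREB loci. Without Nipponbare 0 h replicate 1 alone, WRKY45 (LOC_Os05g25770) passed as lower (adjusted p = 0.0332; 0.00566 to 0.938 over all alternatives). Of 5 proline and trehalose loci, TPP2 (LOC_Os10g40550), a trehalose phosphatase, fell by 2.03 on the log2 scale (SE 0.27, adjusted p = 0.00463), and P5CS1 (LOC_Os05g38150), of proline synthesis, was at 0.56 (adjusted p = 0.0631; 0.0454 with another background correction, and 0.0258 to 0.249 over all alternatives). Adjusted over the list alone 1 rose and 1 fell, and the set did not shift (camera adjusted p = 0.505; adjusted p = 0.643 with an estimated correlation). Without Nipponbare 0 h replicate 1, TPP1 passed as lower too (adjusted p = 0.0459), which made 2 fallen loci. Without either Pokkali 0 h replicate, P5CS2 (LOC_Os01g62900) passed as higher (adjusted p = 0.0412 each; 0.0412 to 0.7 over all alternatives).

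Across all loci, 11964 changed in Nipponbare (26.3%), 6371 of them higher and 5593 lower at 8 h, by a median of 2.38-fold, and 7936 of these changed at least 2-fold. Among loci above background in both groups and apart in every replicate, LOC_Os06g28050 rose by the most, at a log2 change of 8.20 (SE 0.29), followed by LOC_Os07g34570 at 8.09 (SE 0.96). LOC_Os08g16260 at -6.14 (SE 0.80) and LOC_Os09g24370 at -6.10 (SE 0.59) fell by the most. The count was 5751 without Nipponbare 0 h replicate 2, 6385 without 8 h replicate 1 and 4034 without 8 h replicate 2. With no scaling between arrays the median change of all loci moved from 0.05 to -0.17 log2 units and the share of calls that were lower from 46.7% to 66.8%, so the balance of rises and falls is relative to the scaling.

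In Pokkali the same comparison again gave steep rises of dehydrins and LEA proteins. LEA3 rose 83.0-fold (log2 6.37, SE 0.73, n = 2 arrays per group, adjusted p = 0.00313) and RAB16C rose 69.1-fold (SE 0.35 log2 units, adjusted p = 0.00112). RAB16B (LOC_Os11g26780) rose 4.18-fold (SE 0.23 log2 units, adjusted p = 0.00305), SALT 10.1-fold (adjusted p = 0.00322) and RAB16A at least 9.83-fold (adjusted p = 0.00272). RAB16D, not above background at 0 h, rose at least 1.92-fold (adjusted p = 0.0298), so 5 of the 6 LEA and dehydrin loci rose, and 6 adjusted over the list alone (camera adjusted p = 0.000132; adjusted p = 0.0626 with an estimated correlation). The RAB16D call ended without Pokkali 0 h replicate 1 (adjusted p = 0.101), without 8 h replicate 1 (0.0969) and without 8 h replicate 2 (0.132), and ran from 0.0262 to 0.132 over all alternatives. Of the 16 known salt genes 9 rose, and 12 adjusted over the list alone (camera adjusted p = 8.81e-05; adjusted p = 0.0626 with an estimated correlation).

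Abscisic acid synthesis genes rose in Pokkali too. NCED5 rose 4.61-fold (SE 0.18 log2 units, adjusted p = 0.00171), NCED3 6.78-fold (adjusted p = 0.0181) and NCED4 33.5-fold (adjusted p = 0.023), giving 3 of 6 loci, and 4 adjusted over the list alone. The 8'-hydroxylases ABA8OX1, ABA8OX2 and ABA8OX3 were at log2 changes of -0.54, 0.60 and -0.26 and did not pass. The mean of the list was -0.69 on Pokkali 0 h replicate 1 and 0.79 on replicate 2, against 1.66 and 1.71 at 8 h. The outcome for the hydroxylases hung on the 0 h replicate kept: without replicate 1 of both lines at 0 h ABA8OX1 (0.00874) and ABA8OX3 (0.0121) passed as lower, and without replicate 2 of both ABA8OX3 passed as higher (0.0447). ABA8OX2 passed as higher with probes bright on all 8 arrays (0.0499) and with another background correction (0.0461). Over all alternatives ABA8OX1 ran from 0.00874 to 0.869, ABA8OX2 from 0.029 to 0.222 and ABA8OX3 from 0.0121 to 0.931. The set passed with the preset correlation of 0.01 (camera adjusted p = 0.046). It did not pass with an estimated correlation, which was 0.752 (camera adjusted p = 0.463), or with fry (adjusted p = 0.242). The camera pass also ended without either Nipponbare 8 h replicate, without Pokkali 0 h replicate 1 and without Pokkali 8 h replicate 1. The count of risen loci was 1 without Pokkali 0 h replicate 1 (NCED3 adjusted p = 0.0614, NCED4 0.0764), without 8 h replicate 1 (0.0839 and 0.077) and without 8 h replicate 2 (0.0779 and 0.116). Over all alternatives the adjusted p ran from 0.00269 to 0.0839 for NCED3 and from 0.00236 to 0.116 for NCED4.

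Sodium antiporters and NAC factors rose in Pokkali. NHX1 rose 3.83-fold (SE 0.26 log2 units, adjusted p = 0.0045) and SOS1 2.19-fold (adjusted p = 0.00583), so 2 of 4 measured transport loci rose, and 2 adjusted over the list alone. HKT2;1 passed as higher without replicate 1 of both lines at 0 h (0.00713; 0.00713 to 0.955 over all alternatives) and HKT1;1 without replicate 2 of both (0.0259; 0.0259 to 0.966). With the brightest probe of each locus the SOS1 call ended (0.0613; 0.00364 to 0.0613 over all alternatives). NAC10 rose 7.73-fold (SE 0.26 log2 units, adjusted p = 0.00186), NAC5 3.70-fold (adjusted p = 0.00275) and NAC6 3.13-fold (adjusted p = 0.0235), 3 of 4 NAC loci, and 4 adjusted over the list alone. The NAC6 call ended without Pokkali 0 h replicate 1 (0.0856), 8 h replicate 1 (0.0695) or 8 h replicate 2 (0.123), and ran from 0.00409 to 0.123 over all alternatives; SNAC1 was at a log2 change of 1.78 (adjusted p = 0.0963) and passed without either Nipponbare 0 h replicate (0.0465 each) and without replicate 2 of both lines at 0 h (0.0139; 0.00533 to 0.321 over all alternatives). BZIP46 rose 1.96-fold (adjusted p = 0.0155), 1 of 3 bZIP loci, and 2 adjusted over the list alone. Its call ended without Pokkali 0 h replicate 2 (0.0717) or 8 h replicate 2 (0.0909), and ran from 0.00853 to 0.0909 over all alternatives. Without Pokkali 0 h replicate 2, BZIP23 (LOC_Os02g52780) and BZIP72 passed (0.0452 and 0.042), which made 2; over all alternatives BZIP23 ran from 0.00424 to 0.277 and BZIP72 from 0.0203 to 0.746.

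**Figure D1:**
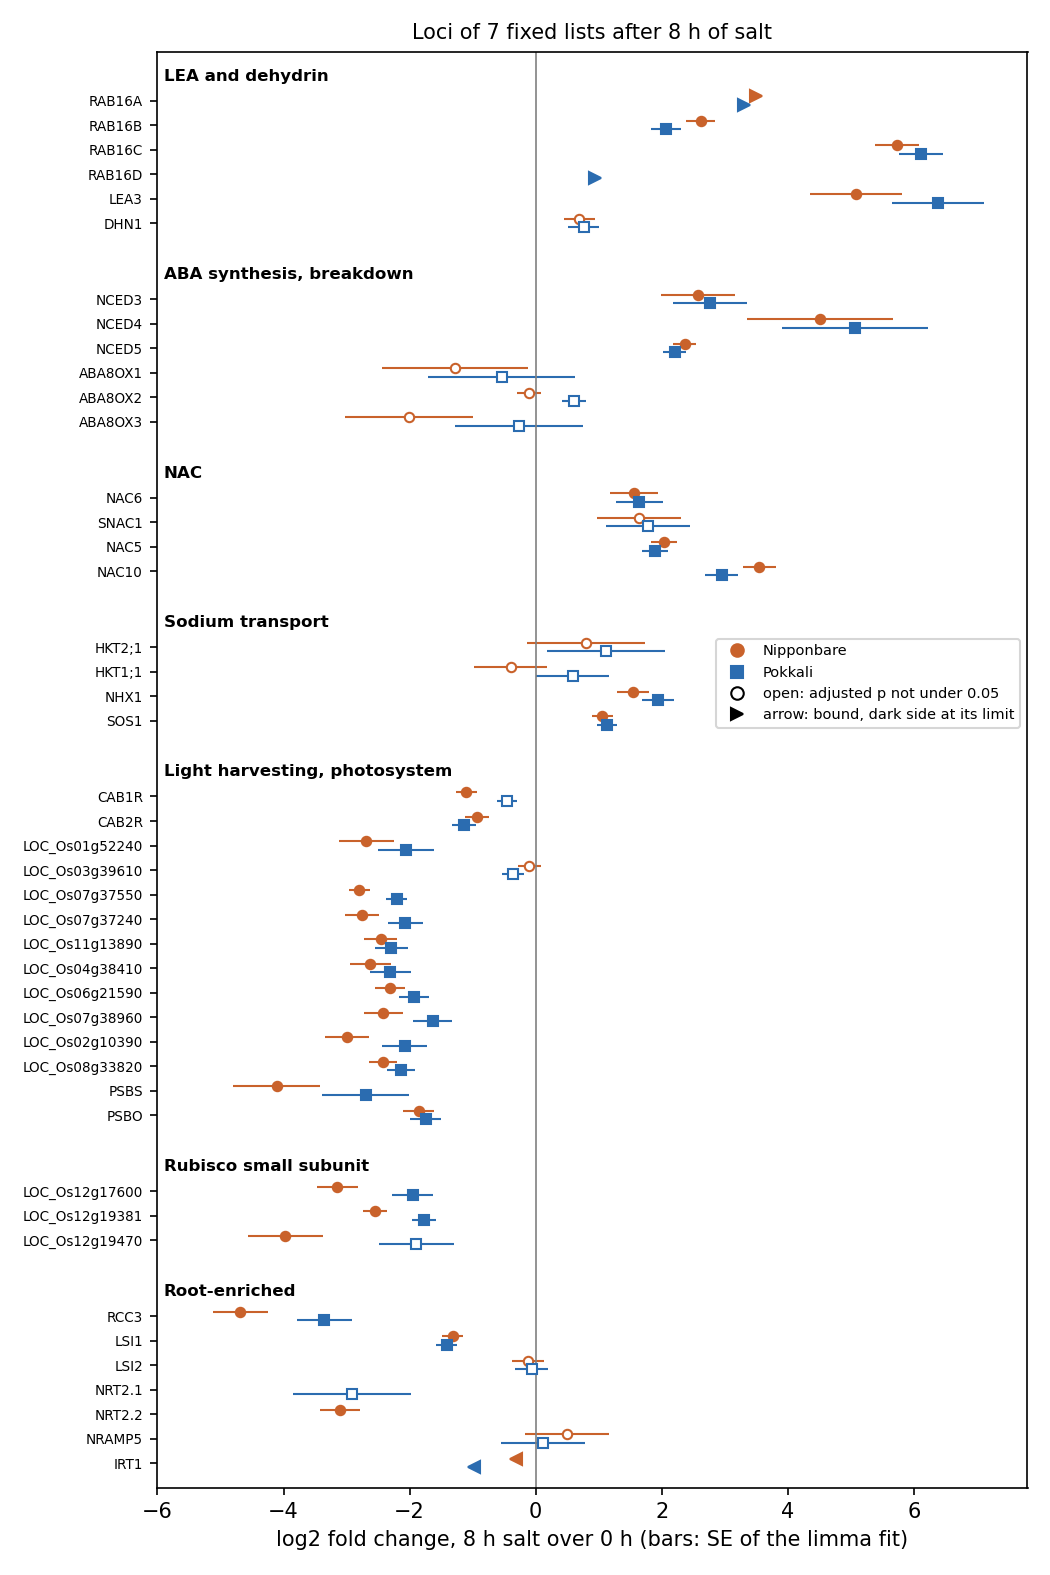
Log2 fold change from 0 h to 8 h of salt (horizontal axis) of the loci of 7 lists in Nipponbare (circles) and Pokkali (squares), with bars for the SE of the fit, open symbols for loci that did not pass and arrows for bounds. RAB16C and LEA3 lie between 5.09 and 6.37 in both lines, and the 14 light harvesting and photosystem loci lie between -4.11 and -0.10 in Nipponbare and between -2.70 and -0.36 in Pokkali.

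Photosynthesis and root transcripts fell in Pokkali as well. Of the 14 light harvesting and photosystem loci 12 fell, and 13 adjusted over the list alone, with a median log2 change of -2.06 (camera adjusted p = 7.6e-09; adjusted p = 0.0626 with an estimated correlation). LOC_Os07g37550 was at -2.20 (SE 0.17, adjusted p = 0.00159), LOC_Os11g13890 at -2.29 (SE 0.26) and PSBO at -1.74 (SE 0.24). PSBS was at -2.70 (SE 0.69, adjusted p = 0.0325), a call that ended without either Nipponbare 8 h replicate (0.059 each), without Pokkali 0 h replicate 2 (0.123), 8 h replicate 1 (0.144) or 8 h replicate 2 (0.0684), and with the Pokkali arrays alone (0.0545), in a range of 0.00751 to 0.144. Of the 3 measured Rubisco small subunit loci 2 fell, and 3 adjusted over the list alone: LOC_Os12g17600 was at -1.95 (adjusted p = 0.00847) and LOC_Os12g19381 at -1.77 (adjusted p = 0.00269), while LOC_Os12g19470 was at -1.89 (adjusted p = 0.0614; 0.0223 without Pokkali 0 h replicate 1, 0.0144 without replicate 1 of both lines at 0 h, 0.0471 without scaling and 0.00866 to 0.215 over all alternatives). Of 7 root-enriched loci 4 passed as lower, among them NRT2.2 without a measured level, and 5 adjusted over the list alone. The set shifted downwards (camera adjusted p = 0.00258, and adjusted p = 0.0626 with an estimated correlation). RCC3 was at -3.35 (SE 0.44, adjusted p = 0.00419), LSI1 at -1.41 (SE 0.17) and IRT1 at least 1.97-fold lower (adjusted p = 0.0097), a call that another background correction ended (0.0803; 0.00619 to 0.0803 over all alternatives). NRT2.2 passed as lower (adjusted p = 0.0292) although it was not above background on any Pokkali array, so no fold is given. A fall of NRT2.2 was thus not measured in Pokkali, and the counts that hold it rest there on signal near background. It was the 1 of 2 nitrate loci that fell, and 2 adjusted over the list alone; the count was 0 without Nipponbare 8 h replicate 1 or 2 (0.0515 each), Pokkali 0 h replicate 1 (0.0619), 8 h replicate 1 (0.113) or 8 h replicate 2 (0.11), and without Pokkali 0 h replicate 2 NRT2.1 took its place (0.0133 against 0.115 for NRT2.2). Over all alternatives NRT2.1 ran from 0.0133 to 0.266 and NRT2.2 from 0.00859 to 0.833.

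None of the DREB, WRKY or TIFY loci passed in Pokkali, and 0 of each passed adjusted over the list alone. Here too the 0 h replicates lay apart: the TIFY mean was -2.02 on Pokkali 0 h replicate 1 and 0.67 on replicate 2, against -0.69 and -0.28 at 8 h. Leaving out replicate 2 of both lines at 0 h gave 2 risen TIFY, 2 risen WRKY and 1 risen DREB loci, and leaving out replicate 1 gave 2 fallen TIFY, 1 fallen WRKY and 2 fallen DREB loci. Of the proline and trehalose loci P5CS1 rose 1.98-fold (SE 0.18 log2 units, adjusted p = 0.011) and TPP2 fell by 1.93 on the log2 scale (SE 0.27, adjusted p = 0.00542), as also adjusted over the list alone (1 rose and 1 fell). The set did not shift (camera adjusted p = 0.465; adjusted p = 0.612 with an estimated correlation). The P5CS1 call ended without Pokkali 8 h replicate 1 (0.0561) or replicate 2 (0.054), and ran from 0.00684 to 0.0561 over all alternatives. Without Pokkali 0 h replicate 1, P5CS2 passed too (0.0386; 0.0386 to 0.973 over all alternatives), and without replicate 1 of both lines at 0 h TPP1 passed as lower (0.0067; 0.00461 to 0.607 over all alternatives).

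**Figure D2:**
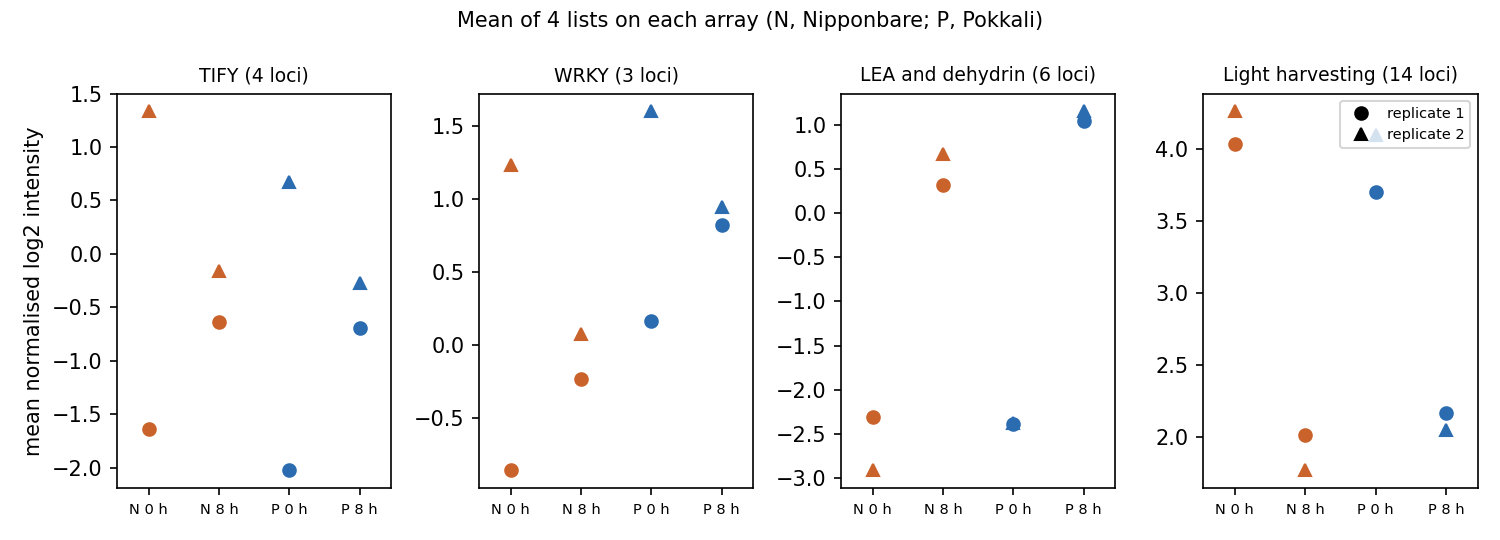
Mean normalised log2 intensity (vertical axis) of 4 lists on each of the 8 arrays, with circles for replicate 1 and triangles for replicate 2. The TIFY mean is -1.64 and 1.33 on the Nipponbare 0 h arrays and -2.02 and 0.67 on the Pokkali 0 h arrays, while the LEA and dehydrin means of the 0 h arrays lie between -2.91 and -2.31.

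In all, 12331 loci changed in Pokkali (27.2%), 6900 of them higher and 5431 lower, by a median of 2.37-fold, and 8120 of these changed at least 2-fold. LOC_Os07g34570 rose by the most, at a log2 change of 8.71 (SE 0.96), followed by LOC_Os02g30910 at 8.43 (SE 0.22). LOC_Os09g24370 at -6.71 (SE 0.59) fell by the most, followed by LOC_Os07g22580 at -5.84 (SE 0.56), which was above background on 1 of the 2 Pokkali 8 h arrays. The count was 6870 without Pokkali 0 h replicate 2, 6999 without 8 h replicate 1 and 4763 without 8 h replicate 2. Without scaling the share of calls that were lower moved from 44.0% to 57.5% and the median change of all loci from 0.08 to -0.07.

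The changes from 0 h to 8 h of salt ran closely together in both lines. Across the 45411 loci the log2 fold changes had a Pearson r of 0.784 and a Spearman rho of 0.744, and the orthogonal slope over the 16379 loci called in either line was 0.996. Of those 16379 loci 91.5% changed with the same sign. In both lines 4052 loci rose, against 968 expected from the separate shares, and 3793 fell, against 669, while 71 were called in opposite directions. The shared risers include RAB16C, LEA3, NCED5, NHX1 and NAC10, and the shared fallers LOC_Os07g37550, PSBO, RCC3 and LSI1. These are correlations across genes, and genes are not independent replicates. Both lines also shared the hour, the slide columns of each time and part of the replicate difference at 0 h (r = 0.536 across genes). Each of these can raise the r and the overlaps, so they do not measure agreement in salt alone. Leaving out single arrays gave an r of 0.729 to 0.777, lowest without Pokkali 0 h replicate 2.

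**Figure D3:**
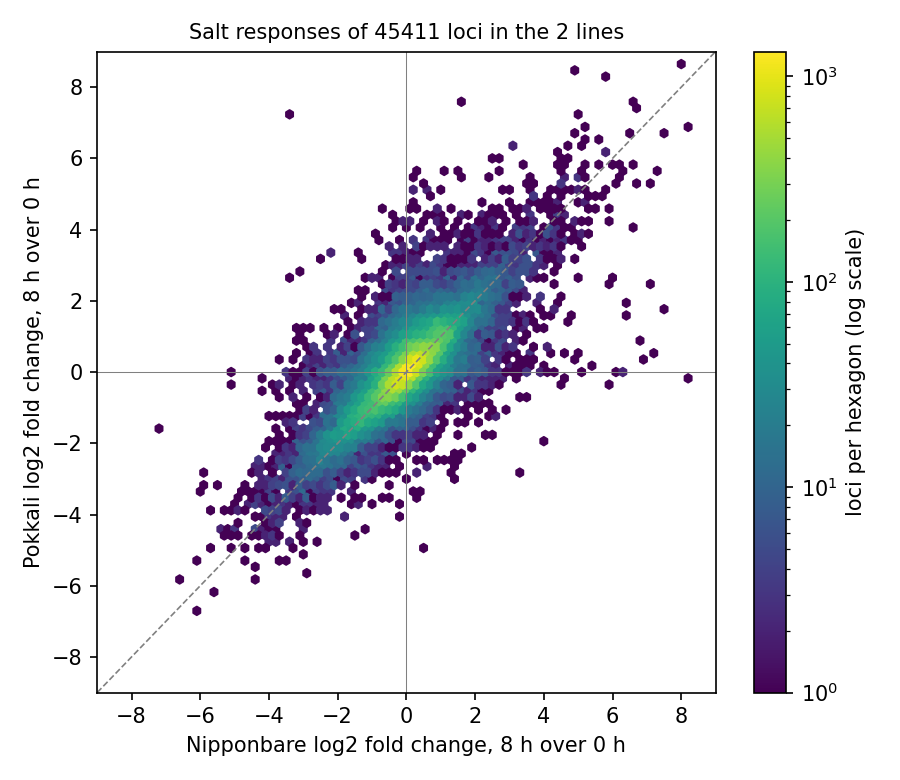
Log2 fold change from 0 h to 8 h of salt in Nipponbare (horizontal axis) and Pokkali (vertical axis), coloured by the number of loci in each hexagon on a log scale; the dashed line marks equal changes. The 45411 loci follow the line with a Pearson r of 0.784.

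A further comparison asked which loci responded differently in the 2 lines, as the interaction of line and salt. None of the 65 measured list loci passed this test, neither the LEA and dehydrin loci nor those of light harvesting, abscisic acid or sodium transport. Among the Rubisco small subunits the fall was shallower in Pokkali by 0.78 to 2.08 log2 units, with adjusted p from 0.365 to 0.472 over all loci, and 3 of the 3 passed adjusted over the list alone. Adjusted over the list alone, 2 nitrate loci (1 higher and 1 lower) passed as well, as did 1 member of the root-enriched list (higher), and 0 of the loci of each other list fixed beforehand. The root-enriched list holds both nitrate loci, and the largest positive difference in each of these lists was the same, at 1.84. The pass in the root-enriched list may therefore be a nitrate locus again and is not counted as a further one. NRT2.1 was not above background on any Nipponbare array and NRT2.2 on any Pokkali array. The salt change of each nitrate locus was thus unmeasured in 1 line, and no difference between the lines can be read from it. None of the 6 sets passed; the light harvesting set, with a shallower fall in Pokkali, had the smallest p (camera adjusted p = 0.0813; adjusted p = 0.96 with an estimated correlation). That set passed with another background correction (0.00595) and without Nipponbare 0 h replicate 1 (0.0306), Nipponbare 8 h replicate 1 (0.00763), Pokkali 0 h replicate 2 (0.0135) or Pokkali 8 h replicate 2 (0.0112), and its adjusted p ran from 0.00595 to 0.977 over all alternatives. Each of these 5 passes was lost again with the correlation estimated (adjusted p = 0.815, 0.615, 0.831, 0.827 and 0.852 with an estimated correlation, in the same order). The abscisic acid set (camera adjusted p = 0.879) passed without Nipponbare 0 h replicate 1 (0.0306; adjusted p = 0.615 with an estimated correlation) and without replicate 1 of both lines at 0 h (0.0103; adjusted p = 0.7 with an estimated correlation), in a range of 0.0103 to 0.988.

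Over all loci 157 passed, 92 with a larger log2 change in Pokkali and 65 with a smaller one, and 4726 had an unadjusted p under 0.05. With replicate number as a block the count was 30 (12 higher and 18 lower), and with a replicate block within each time it was 1. Of the 4 loci named next, only LOC_Os08g30800 passed with the first block and none with the second. LOC_Os11g19864 went from -2.56 to 4.68 in Nipponbare and from 2.03 to 2.55 in Pokkali, an interaction of -6.73 (SE 0.71, adjusted p = 0.0345). LOC_Os02g33470 went from -2.54 to 4.36 in Nipponbare and from 1.51 to 1.77 in Pokkali, an interaction of -6.64 (SE 0.71, adjusted p = 0.0351). In the other direction LOC_Os12g14660 went from -4.11 to -3.59 in Nipponbare and from -2.64 to 2.53 in Pokkali (4.64, SE 0.59, adjusted p = 0.04997), and LOC_Os08g30800 had an interaction of 4.53 (SE 0.42, adjusted p = 0.0284). Of the 157 loci 42 (26.8%) were not above background on any array of 1 line, against 3.62% of all loci tested. Each of the 157 also differed between the lines at 0 h or 8 h. That follows from the tests, since the interaction is the difference of these line differences at a stricter threshold. The count was 77 without Nipponbare 0 h replicate 1, 27 without Nipponbare 0 h replicate 2, 4 without Nipponbare 8 h replicate 1, 3 without Nipponbare 8 h replicate 2, 27 without Pokkali 0 h replicate 2 and 0 without Pokkali 8 h replicate 1 or replicate 2. Each of the 4 named calls ended when any 1 of the 8 h arrays was left out (adjusted p = 0.0969 to 0.197). Without Nipponbare 0 h replicate 1 or 2, LOC_Os12g14660 (0.101 and 0.135) and LOC_Os08g30800 (0.0567 and 0.0626) were lost, without Pokkali 0 h replicate 1 or 2, LOC_Os11g19864 (0.0638 and 0.0837) and LOC_Os02g33470 (0.0653 and 0.0847), and LOC_Os12g14660 also without Pokkali 0 h replicate 2 (0.0566). With no filter on dim probes LOC_Os12g14660 (0.0717), LOC_Os11g19864 (0.0513) and LOC_Os02g33470 (0.0521) were lost. LOC_Os12g14660 was also lost with probes bright on all 8 arrays (0.0602), with outlier spots kept (0.0504) and without replicate 1 of both lines at 0 h (0.0503). Without replicate 2 of both lines at 0 h all 4 were lost (0.102 to 0.12). Over all alternatives the adjusted p ran from 0.0168 to 0.197 for LOC_Os12g14660, from 0.00525 to 0.146 for LOC_Os08g30800, from 0.019 to 0.166 for LOC_Os11g19864 and from 0.0173 to 0.166 for LOC_Os02g33470.

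Before salt, most listed stress and photosynthesis genes stood at levels that did not differ by the test between the lines. None of the 6 LEA and dehydrin, 4 NAC, 4 measured transport or 16 known salt loci differed at 0 h with all arrays. RAB16A, not above background in either line at 0 h (adjusted p = 0.131), passed as higher in Pokkali without Nipponbare 0 h replicate 1 (0.0343) and without replicate 1 of both lines at 0 h (0.0227), in a range of 0.0134 to 0.396. NAC10, at 0.75 (adjusted p = 0.112), passed as higher without either Nipponbare 8 h replicate (0.045 each; 0.045 to 0.454 over all alternatives). The signals of the paralogous high-affinity nitrate transporters stood in opposite order. NRT2.1 was at least 32.2-fold higher in Pokkali (adjusted p = 0.0035) and NRT2.2 at least 26.6-fold lower (adjusted p = 9.81e-05), each not above background in the lower line. NRT2.1 was dark on every Nipponbare array and NRT2.2 on every Pokkali array. A difference of sequence at the probe, or an absent locus, could give the same signals and was not tested for this pair. The light harvesting locus LOC_Os07g37240 was at a log2 difference of -3.64 (SE 0.27, adjusted p = 0.000337), lower in Pokkali. The same limit on sequence at the probe holds for this locus and for the other single loci lower in Pokkali, at 0 h and at 8 h. Smaller differences passed for CAB1R (LOC_Os09g17740) at -0.91 (adjusted p = 0.0125) and NCED5 at 0.93 (adjusted p = 0.017). The CAB1R call ended without Nipponbare 0 h replicate 2 (0.0631), without Pokkali 0 h replicate 1 (0.0569) and with the 0 h arrays alone (0.0656), in a range of 0.00376 to 0.0863. The NCED5 call ended without replicate 1 of Nipponbare (0.0754) or Pokkali (0.0736) at 0 h and with the 0 h arrays alone (0.0884), in a range of 0.00921 to 0.129.

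At 0 h 7632 loci differed between the lines, 3052 higher and 4580 lower in Pokkali, and 5803 differed at least 2-fold. LOC_Os06g38210 at -10.29 (SE 0.21, adjusted p = 3.39e-06) and LOC_Os03g03510 at -10.33 (SE 0.65), above background on 1 of the 2 Pokkali 0 h arrays, were lower by the most, and LOC_Os12g29605 at 9.28 (SE 2.09, adjusted p = 0.0286) and LOC_Os11g46860 at 9.14 (SE 0.51, adjusted p = 9.91e-05) were higher by the most. An absent locus or a difference of sequence at the probe could give such signals too, and neither was tested for these loci. The LOC_Os12g29605 call ended without Nipponbare 0 h replicate 1 (0.112) or 2 (0.0805), Pokkali 0 h replicate 1 (0.0735) or 2 (0.113) and either Pokkali 8 h replicate (0.0593 each), in a range of 0.000756 to 0.195. Of all calls at 0 h the share lower in Pokkali was 54.6% with quantile normalisation, 55.6% with median scaling, 50.2% with another background correction and 76.0% without scaling. With the 0 h arrays alone the count was 4155, and without replicate 2 of both lines it was 4929.

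After 8 h of salt the signals of the same nitrate pair differed between the lines, with the same limit on sequence at the probes. Of 14 light harvesting loci 2 were higher and 1 lower in Pokkali (2 and 1 adjusted over the list alone), and of 3 Rubisco loci 2 were higher (3 adjusted over the list alone), where 22.0% of all loci differed; no set test was made between the lines. NRT2.1 was at least 3.52-fold higher (adjusted p = 0.0292) and NRT2.2 at least 3.16-fold lower (adjusted p = 0.000453), and LOC_Os07g37240 was again lower, at -2.95 (SE 0.27, adjusted p = 0.000752). Higher in Pokkali were PSBS at 2.66 (SE 0.69, adjusted p = 0.0387), the light harvesting locus LOC_Os06g21590 at 1.05 (SE 0.24, adjusted p = 0.0243), the Rubisco small subunits LOC_Os12g19470 at 2.28 (SE 0.60, adjusted p = 0.0405) and LOC_Os12g17600 at 1.52 (SE 0.32, adjusted p = 0.0201), P5CS1 at 0.86 (adjusted p = 0.0178) and NCED5 at 0.77 (adjusted p = 0.0281). RAB16D, not above background in Nipponbare at 8 h, was at least 1.86-fold higher (adjusted p = 0.0263). The calls of PSBS, LOC_Os12g19470, P5CS1, NCED5 and NRT2.1 ended when any 1 of the 4 8 h arrays was left out (adjusted p = 0.0675 to 0.189), and that of LOC_Os12g17600 without Nipponbare 8 h replicate 2 (0.11) or Pokkali 8 h replicate 1 (0.0718). Without Nipponbare 8 h replicate 2, Pokkali 8 h replicate 1 or Pokkali 8 h replicate 2 the calls of RAB16D (0.124, 0.0983 and 0.123; 0.0175 to 0.124 over all alternatives) and LOC_Os06g21590 (0.114, 0.122 and 0.0655; 0.0103 to 0.122) ended, the latter also without scaling (0.0649). With another background correction neither nitrate locus passed at 8 h (0.333 for NRT2.1 and 0.131 for NRT2.2).

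With the 4 8 h arrays fitted alone, apart from the wider spread of the 0 h replicates, 11748 loci differed at 8 h, and 11 named loci were gained and 0 lost. Higher in Pokkali in that fit were HKT1;1 (adjusted p = 0.00818), WRKY45 (0.00754), WRKY71 (LOC_Os02g08440; 0.0119), DREB1B (LOC_Os09g35010; 0.0239), NCED3 (0.0314), ABA8OX3 (0.0319), RCC3 (0.0308) and LOC_Os12g19381 (0.0323), and lower were DREB1C (LOC_Os06g03670; 0.00777) and TIFY11C (LOC_Os03g08320; 0.0334). With all arrays none of these passed (adjusted p = 0.0559 for LOC_Os12g19381, 0.154 for RCC3, 0.178 for HKT1;1 and 0.258 to 0.663 for the others). Over all alternatives their adjusted p ran from 0.00257 to 0.828. The last gained locus was PCL1, of the clock list added later, higher in Pokkali (0.00382, against 0.0961 with all arrays), which also passed with another background correction (0.000707) and without either Nipponbare 0 h replicate (0.00673 each), in a range of 0.000707 to 0.297. LOC_Os12g19381 also passed with quantile normalisation (0.0446), with median scaling (0.0438) and without either Nipponbare 0 h replicate (0.0482 each). NHX1, not passing with all arrays (0.0627), passed as higher in Pokkali with another background correction (0.0401), quantile normalisation (0.0464), median scaling (0.0492) and without Nipponbare 8 h replicate 2 (0.0489), in a range of 0.0181 to 0.265.

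At 8 h 9973 loci differed, 4780 higher and 5193 lower in Pokkali, and 6991 differed at least 2-fold. LOC_Os02g54240 at 9.58 (SE 0.35) and LOC_Os11g11694 at 8.53 (SE 0.30) were higher in Pokkali by the most. LOC_Os09g17560 at -11.99 (SE 0.39), above background on 1 of the 2 Pokkali 8 h arrays, and LOC_Os06g38210 at -10.59 (SE 0.21) were lower by the most. Sequence at the probe and absence of the locus were not tested for these loci either. The line differences at 0 h and 8 h had a Pearson r of 0.842 across genes, with 3424 loci lower in Pokkali at both times (524 expected from the separate shares), 2131 higher at both (321 expected) and 41 in opposite directions. The count was 5131 without Nipponbare 8 h replicate 1, 5026 without Nipponbare 8 h replicate 2, 5730 without Pokkali 8 h replicate 1 and 5234 without Pokkali 8 h replicate 2. Without scaling the share of lower loci moved from 52.1% to 65.0%.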

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

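The tests of shared handling and of 8 h RNA in the 0 h samples, and the alternatives that leave out 2 arrays, use another background correction or block replicates within each time, were chosen after the result was seen.

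A test of the difference between the salt responses of the lines passed for 157 loci. The 4 named ones had differences of 4.64 (LOC_Os12g14660), 4.53 (LOC_Os08g30800), -6.73 (LOC_Os11g19864) and -6.64 (LOC_Os02g33470) log2 units, Pokkali change less Nipponbare change. These calls were fragile: leaving out any 1 of the 8 h arrays left 0 to 4 loci and ended all 4 named calls (adjusted p = 0.0969 to 0.197).

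The first pattern is the change of 11964 and 12331 loci between 0 h and 8 h, which coincides with a change of the time of day. If the hour contributed, genes of the circadian clock were predicted to move in the same direction in both lines. Of 8 measured clock loci, 4 were called higher at 8 h in both lines, just the share set beforehand as the minimum. The call of PRR59 (LOC_Os11g05930) in Pokkali held in 12 of 23 alternatives (adjusted p = 0.00992 to 0.146) and ended without either Nipponbare 8 h replicate (0.0758 each), Pokkali 0 h replicate 2 (0.141) or Pokkali 8 h replicate 1 (0.146) or 2 (0.142); PRR59 in Nipponbare ended without Nipponbare 0 h replicate 2 (0.0596) or 8 h replicate 1 (0.0575) or 2 (0.0636), PCL1 in Nipponbare without either Nipponbare 8 h replicate (0.0666 and 0.063) and PRR95 in Pokkali without Pokkali 0 h or 8 h replicate 2 (0.0533 and 0.0825), and any of these losses leaves the share under the minimum. Time of day may contribute to the changes, including those of the light harvesting list, and salt stays open as well because no unsalted 8 h group separates them; the rises of the LEA and SALT loci were not tested against the hour.

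The second pattern is that replicate 2 of both lines at 0 h stood apart from replicate 1: 1740 loci differed over 2-fold between the 0 h replicates in both lines (321 expected from the separate shares), 1666 of them in the same direction. An effect of labelling, hybridisation or array position that reaches spike-in probes too is argued against. The 8 bright spike-in probes varied between these arrays by at most 0.132 of the SD of genes of the same brightness. An effect particular to the sample RNA or to single gene probes cannot be seen in these 8 probes and stays open. A mixture with 8 h RNA is argued against too: of 1020 loci over 2-fold higher in replicate 2 in both lines, 77.7% lay above both 8 h arrays of their line, which no mixture gives (27.2% for loci higher in replicate 1); an earlier test on the LEA median (-0.13, 95% bootstrap interval -1.04 to 0.12, against a salt change of 3.27) had left it undecided. Handling, day or stress shared by the 0 h samples of both lines was neither supported nor excluded: the r across genes of 0.536 between the replicate differences of the lines at 0 h (0.218 at 8 h, at most 0.112 between groups of different time) restates the pattern and would follow from any shared cause. No biological explanation was tested, since the labels name no difference between the replicates.

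The third pattern is that line differences at 0 h leaned towards lower in Pokkali (4580 of 7632). Scaling between arrays could account for part of it, since quantile normalisation brought the share to 54.6% and median scaling to 55.6%. Among differences of at least 2-fold it was still 58.6% with quantile normalisation. With another background correction the share was 50.2%, so the lean also hung on the background correction. Of the calls, 1151 lower ones were dark in Pokkali at 0 h, against 343 higher ones dark in Nipponbare. The cause of this was not tested. Whether sequence mismatch between Pokkali and the probes contributes was left open. Probes of the same locus diverged more in the line effect than in the salt effect (SD ratio 1.40, 95% bootstrap interval 1.18 to 1.63, 2147 loci). That SD has no direction and is not scaled to the size of the effects, so it cannot explain a lean towards lower. Real differences of expression between the lines stay open and were not tested.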

How the results depend on the processing

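The alternatives with another background correction, with replicates blocked within each time and without a pair of 0 h arrays were chosen after the results were seen; the others were planned. Of 385 named fold changes with 8724 alternative values, 8310 kept their direction and side of the threshold or stayed below it, 222 lost and 188 gained a call, and 4 reversed; none of those 4 fold changes, in 3 loci, had passed with all arrays. These were ABA8OX3 and DREB1C (LOC_Os06g03670) in Pokkali without both 0 h replicate 2 arrays (0.83 and 0.82), and DREB1C and WRKY71 (LOC_Os02g08440) in Nipponbare without both 0 h replicate 1 arrays (-0.74 and -0.89). A minimum of 2-fold left 7936 loci in Nipponbare and 8120 in Pokkali, by its construction. Leaving out 1 array gave 4034 to 12255 salt loci in Nipponbare, 4763 to 12020 in Pokkali, 0 to 179 for the interaction, 5302 to 6459 line differences at 0 h and 5026 to 9983 at 8 h; fewer arrays leave fewer degrees of freedom. The interaction count was 52 with no filter, 49 with probes bright on all 8 arrays, 1 without both 0 h replicate 2 arrays and 60 without both replicate 1 arrays. Line differences at 0 h numbered 4155 with the groups compared alone and 4929 without both 0 h replicate 2 arrays. The labels link replicates of different groups by number alone, so the block is a check, not the design; replicate differences correlated across genes with r = 0.536 between the lines at 0 h and 0.218 at 8 h, and with 0.0614 to 0.112 between times. With the block the salt counts were 13877 and 14397 and the interaction count 30 (12 higher and 18 lower); SNAC1, DHN1 and BZIP23 passed as higher in both lines (adjusted p = 0.0383, 0.0269 and 0.0362 in Nipponbare; 0.0298, 0.0199 and 0.0186 in Pokkali), as did P5CS1 in Nipponbare (0.0491). That made 4 of 4 NAC loci in each line, and 5 and 6 of the 6 LEA and dehydrin loci. The named interactions did not pass with it, except LOC_Os08g30800 (LOC_Os12g14660 0.0885, LOC_Os11g19864 0.0698, LOC_Os02g33470 0.0709). Of the named fold changes it gained 4 and lost 1 salt call in Nipponbare, gained 5 in Pokkali and gained 3 line differences at 0 h. With the block set within each time, centred there, the salt counts were 17947 and 18443. The interaction count was 1, which was none of the named loci (0.0566 to 0.0889). This block gained 17 and 14 named salt calls, 9 line differences at 0 h, RAB16A (0.0134) and CIPK24 (0.0277) among them, and 15 at 8 h. It takes the replicate difference shared by the lines within a time out of the residual spread. A comparison of 0 h with 8 h has to face that difference, so the salt p-values of this fit are too small. Its salt counts and gained salt calls are therefore no evidence of more changes, and the ranges over all alternatives include this fit. The same holds for comparisons with 0 h in the fits without a pair of 0 h arrays, whose spread comes from the narrower 8 h pairs alone.

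Of 6 sets, 4 passed in Nipponbare and 5 in Pokkali, 4 to 5 in each without 1 array, and 0 in each with an estimated correlation. With fry 4 passed in each line and 0 for the interaction. For the interaction the set count of 0 became 1 with normexp, 1 with a replicate block (light harvesting, 0.0352; adjusted p = 0.967 with an estimated correlation), 1 without both 0 h replicate 1 arrays, and 0 to 2 without 1 array. The r between the lines was 0.840 with normexp, 0.846 with probes bright on all 8 arrays and 0.729 to 0.777 without 1 array, against 0.784. The cause of these shifts was not tested where the alternative does not itself remove loci or arrays. Counts of the 5 contrasts stayed within 1.5 times under quantile, median and no scaling, single probes, the brightest probe, kept outlier spots and robust variance. Loci dark in 1 group allow a bound alone, and 7519 probes were too dim to test. The planned normexp on mean signals and the slide or scan block were not run.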

Other observations

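The list of clock loci was chosen after the data were seen and before its values were computed; the other tests here were chosen before their results were seen.

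Clock genes differed between 0 h and 8 h. PRR1 (LOC_Os02g40510), the rice counterpart of the evening gene TOC1, rose by 3.02 log2 units in Nipponbare (SE 0.17, adjusted p = 0.000928) and 2.42 in Pokkali (adjusted p = 0.0014). PCL1 (LOC_Os01g74020) rose by 5.05 and 7.30 (adjusted p = 0.0134 and 0.00449), PRR95 (LOC_Os09g36220) by 2.23 and 1.67 (adjusted p = 0.00562 and 0.0134) and PRR59 by 1.46 and 0.95 (adjusted p = 0.0112 and 0.043). In Nipponbare 5 of 8 clock loci rose (6 adjusted over the list alone), and in Pokkali 4 (4 adjusted over the list alone). The Nipponbare count was 3 without Nipponbare 0 h replicate 2 and 2 without either Nipponbare 8 h replicate, and the Pokkali count was 2 without Pokkali 0 h replicate 2 or 8 h replicate 2. PRR37 (LOC_Os07g49460) was higher in Pokkali at 0 h by 1.36 (SE 0.20, adjusted p = 0.00579), and its interaction of -1.25 did not pass (adjusted p = 0.181); adjusted over the list alone 1 clock locus passed the interaction, as lower.

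A hypothesis was that salt-responsive loci were already shifted in Pokkali at 0 h in the direction of the salt response. It was tested as the correlation across genes of the line difference at 0 h with the Nipponbare salt change, computed from separate Nipponbare 0 h arrays. The r was -0.0937 in one split and 0.0548 in the other, both below the bound of 0.1 set beforehand. The replicate difference at 0 h is shared by the lines (r = 0.536 across genes), and it pulls both r downwards. The test therefore cannot exclude such a shift.

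Loci bright on all 4 Nipponbare arrays and dark on all 4 Pokkali arrays numbered 637, against 214 in reverse. A hypothesis was that some of the 637 lie in blocks absent from or divergent in Pokkali. They formed 24 adjacent pairs along the loci of the array, against a mean of 7.72 and a highest of 20 in 10000 random placements (permutation p = 0.0001, the smallest these can give), with a longest run of 3. The 214 formed 1 pair, against a mean of 0.875 (permutation p = 0.591). The excess of neighbours is in line with local absence or divergence of sequence for some loci, and may also hold neighbouring genes of shared family or regulation, which was not tested.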
